A study of Phycomyces blakesleeanus with 24 samples.

How the data were processed

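RNA of wild type and ΔL51 Phycomyces blakesleeanus was extracted with Trizol and amplified with a MessageAmp II kit, per the labels' protocols. The series lists 24 libraries in 8 groups of strain, structure and light, with 3 biological replicates each per the series design text. Bowtie and edgeR were used by the authors, per the submitters' processing notes, with versions not given. The genome build, annotation, counting rule and filters were not given in the sources used here. Per the series design text, wild type dark mycelium replicate 3, wild type dark sporangiophore replicate 3, wild type light sporangiophore replicate 2 and mutant dark sporangiophore replicate 2 were left out of the authors' final edgeR analysis for their greater dispersion. That choice rests on the outcome and lowers the spread seen by the test.

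The 4 deposited tables each hold one light against dark comparison by the authors. Per the file headers, they give the log2 fold change, the average log2 CPM, the likelihood ratio score of the authors' edgeR model, its p-value and the FDR. The deposited p-value was checked to equal the chi-square tail of the likelihood ratio with 1 degree of freedom, and the deposited FDR to equal the Benjamini-Hochberg adjusted p-value over the table. Values per library, counts and depth were not analysed here, so no count model, replicate spread or counting interval could be computed. The wild type tables and the mutant sporangiophore table share one log2 CPM value for each of 14410 genes, so 3 tables appear to come from one fit. The mutant mycelium table differs in log2 CPM for all 14162 shared genes and comes from another. The direction of the fold is taken from the title of each table. A fold of exactly 0 was listed for 3193 genes of wild type mycelium, 9 of wild type sporangiophores, 2793 of mutant mycelium and 0 of mutant sporangiophores.

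The plan, fixed before the data were examined, was a count test in each comparison, with the authors' FDR under 0.05 to be reported as theirs where only their comparison was given. That second branch was used, and no gene was retested for the main calls of the 4 comparisons. Contrasts between dark groups could not be made. The IDs are numbers without names. They were matched to the numeric part of locus tags in a symbol table of assembly Phybl2, where 14355 of 14410 (99.6%) matched, against 8.26% of the numbers in the same range being locus tags. Symbols were found for 208 of these genes, and 213 of 16850 genes in the symbol table have one. As the authors' build was not given, no coordinates are printed, and the gene span was used for checks of length only.

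Named genes were chosen by a rule fixed before the data were examined, with departures. The plan named IDs without a symbol only where no names could be paired, yet they were added here. It also had no test of differences without counts, so genes named for differences rest on the approximate test described below. In each comparison they were the 8 largest rises and 6 largest falls among symbol-bearing genes with an FDR under 0.05 and a log2 CPM of at least the median. To these were added up to 4 called members of each list that passed its test, all light sensing genes, 3 genes in each direction for each difference, and 2 rises and 2 falls among IDs without a symbol under the same limits of FDR and log2 CPM. Other genes printed here were chosen after their values were seen.

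Gene lists for light sensing, carotene and isoprenoid synthesis, protein kinases, G proteins and mitochondrial respiration were fixed as themes before the data were examined. Their symbols were assigned once the symbol table was at hand, and carC, CarG2, hmgR and ippI/dmappS were added on the theme. Lists for alternative NADH dehydrogenases, the tricarboxylic acid cycle, 2-component signalling, RNA silencing and cAMP-dependent kinase regulatory subunits were made afterwards but before their values were looked up, although the top rows of each table, including that of WcoA, had been seen. RNA silencing had 2 measured genes and was not tested. Planned lists for heat shock, oxidative stress, DNA repair, cell wall, transcription factors, ribosomal proteins, transporters, proteases, cytoskeleton, cell cycle and lipid metabolism had too few symbols to be tested, and structure markers needed counts. Each list was compared with all other genes of its table by Fisher's exact test per direction, two-sided, giving 72 tests with Benjamini-Hochberg adjustment, of which 10 passed 0.05. List medians were set against 10000 random lists drawn from the 60 nearest genes of each member in log2 CPM, or in log2 CPM and gene span. Fisher's exact test treats genes as independent, so its p-values do not measure variation between cultures. Tests with an estimated correlation need counts and were not run.

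The approximate standard error of a fold was its absolute value divided by the square root of the likelihood ratio. Differences between 2 comparisons were tested as a normal deviate of the difference over the combined approximate standard error, with Benjamini-Hochberg adjustment. This test was chosen after seeing the data, as the plan had no test without counts, and genes with a fold of 0 in either table were left out. On simulated counts with the library numbers of the mycelium strain difference, over 14410 genes and with a fixed dispersion known to the test, 5.47% of unchanged genes had an unadjusted p under 0.05 and 5 were called falsely. Of genes changed by 2 on the log2 scale, 12.0% were called, and of those changed by -3, 50.0%, so differences of 2 were mostly missed in this simulation. Its depth was assumed, and far fewer genes were changed in it than were called in the data, which makes the adjustment stricter. These shares therefore do not give the power of the test in the data. The approximate 95% interval of the difference held 0 for 92.6% of unchanged genes. Genes without an approximate standard error were counted there as not holding 0, so this share understates the coverage. In the share under 0.05 the same genes were counted as not under it. With 2 and 2 against 2 and 3 libraries, as in the sporangiophore and structure differences, these values were 5.29%, 2 false calls, 12.0%, 38.0% and 92.7%. In a simulation of lists on a trend, 3 of 60 random lists fell outside the central 95%, and a rise of 1.5 was returned as 1.32 after the trend was taken out.

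Alternatives fixed beforehand were an FDR under 0.01, an absolute log2 fold change of at least 1 and a log2 CPM of at least 1. Alternatives chosen after seeing the data were an adjustment without genes at a fold of 0, an adjustment over genes of all 4 tables, a log2 CPM of at least the table median, centring on the median of genes with a fold other than 0, removal of a lowess trend (fraction 0.3) on log2 CPM and gene span, the likelihood ratio referred to an F distribution, and a turned sign of the mutant sporangiophore table for the strain difference. Centring and trend removal retested each changed fold as a normal deviate over its approximate standard error. The Benjamini-Hochberg adjustment was then repeated without genes at a fold of 0. Leaving those genes out of the adjustment by itself gave 2200 calls in wild type mycelium in place of 2024. The F reference used 1 and 12 degrees of freedom, the 20 kept libraries less 8 groups, and its p-values were adjusted anew. The mutant mycelium table came from another fit, and which libraries entered each fit was not given. The degrees of freedom are therefore unknown, and 12 may be too many for all 4 tables. Fewer degrees of freedom would leave fewer calls. Intervals for the correlation and covariance of the sporangiophore tables by quintile of log2 CPM came from 1000 bootstrap resamples of genes. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.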

Results

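RNA was measured by sequencing in Phycomyces blakesleeanus, a filamentous fungus of the Mucoromycota whose sporangiophores (aerial stalks that carry the spores) respond to light. The series held 24 libraries from a wild type strain and from ΔL51, which the labels call a photoreceptors mutant. For each strain, mycelium and sporangiophores were grown on potato dextrose agar in darkness or in light, with 3 biological replicates in each of the 8 groups. The study set aside 4 libraries for their greater dispersion, a choice made on the measured outcome, and 20 were kept. Wild type mycelium then had 2 dark and 3 light libraries, and wild type sporangiophores 2 dark and 2 light. Mutant mycelium had 3 dark and 3 light libraries, and mutant sporangiophores 2 dark and 3 light. The series title concerns signalling pathways and genome duplication, and the comparisons address which genes differ between light and dark in each strain and structure. Each comparison came as one of the authors' deposited tables, with a fold change, an average log2 CPM (reads scaled to library size), a likelihood ratio, a p-value and an FDR per gene. Values per library and total counts were not analysed here, so the depth is unknown and fold changes are given without a spread between replicates. Among genes called at an FDR under 0.05, the approximate standard error of log2 fold change, taken from the fold change and its likelihood ratio, had a median of 0.40 in wild type mycelium, 0.41 in wild type sporangiophores, 0.48 in mutant mycelium and 0.36 in mutant sporangiophores. Positive values are read as higher in light, from the titles of the tables, since the headers do not state the direction.

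**Figure D1:**
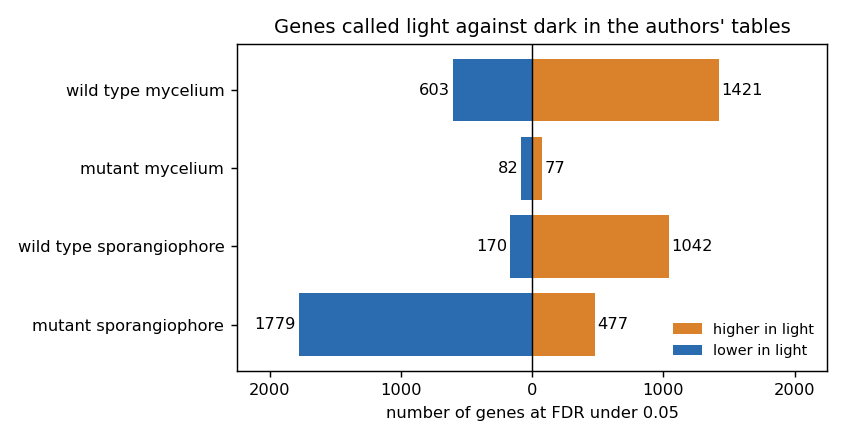
Number of genes at an FDR under 0.05 in each of the authors' deposited tables (horizontal axis, genes; left, lower in light; right, higher in light) for the 4 strain and structure pairs. Higher calls exceed lower calls in both wild type structures, and in mutant sporangiophores 1779 genes are lower against 477 higher. Centring the wild type mycelium folds on their median turns that split to 907 higher and 1344 lower.

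In wild type mycelium, genes of the light sensing list rose in light. According to the authors' deposited table, WcoA, a homolog of the photoreceptor White Collar 1, rose 38.8-fold (log2 fold change 5.28, FDR 6.5e-45), with an approximate 95% interval of 4.57 to 5.98. WctD and WctB, relatives of White Collar 2, the partner protein of that photoreceptor, had log2 fold changes of 6.61 (FDR 1.3e-30) and 8.45 (FDR 4.1e-11) in the authors' deposited table. WctB had an average log2 CPM of 3.89, and such a fold can stand for few or no reads in the dark. MadB, a White Collar 2 gene, rose by 0.96 (FDR 0.0061) and WctC by 1.30 (FDR 0.0359) in the authors' deposited table. MadA, a White Collar 1 gene, had a log2 fold change of -0.63 (FDR 0.166) there. Of the 6 measured light sensing genes, 5 were called higher and 0 lower, against 9.83% of the other genes called higher (Fisher's exact test, adjusted p = 9.2e-04). Adjusted over the list alone, 5 were higher and 1, MadA, was lower. With the folds centred on their median, 3 were higher (WcoA, WctD and WctB) and MadA was lower.

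Other signalling genes also changed in wild type mycelium. Among 36 protein kinases, 10 were called higher and 0 lower (Fisher's exact test, adjusted p = 0.0156), and adjusted over the list alone 10 were higher. The list median of 0.72 lay at the 96.2 percentile of random lists matched on log2 CPM and at the 89.9 percentile of those matched on log2 CPM and gene span, inside the central 95% of both. With the trend on expression level and gene span taken out, 5 kinases were higher and 2 lower, and with the likelihood ratio referred to an F distribution 4 were higher and 0 lower. In the authors' deposited table CaMK7, of the calcium and calmodulin-dependent kinase family by its symbol, had a log2 fold change of 3.93 (FDR 1.4e-13). PPK3 (4.01), PPK5 (3.81), PPK2 (5.82) and PKC1 (2.14), a protein kinase C by its symbol, were called higher in the same authors' deposited table. After centring, 6 kinases were higher and 1 lower, and the list no longer passed when a log2 fold change of at least 1 was required (adjusted p = 0.0918). Of 11 G protein subunits, 1 was higher and 3 were lower, which did not pass the list test (adjusted p = 0.0612). Gpb3, a G protein beta subunit by its symbol, rose by 6.73 (FDR 2.1e-04) and Gpa1B, an alpha subunit, fell by 1.83 (FDR 0.0075) in the authors' deposited table. RdRP-1a, an RNA-dependent RNA polymerase, rose by 2.55 and Cam1 fell by 1.64 in the authors' deposited table.

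Metabolic genes of wild type mycelium moved both ways. Of 24 tricarboxylic acid cycle genes, 7 were higher and 1 lower (Fisher's exact test for higher calls, adjusted p = 0.0494). In the authors' deposited table these included PbFumHa (2.13), PbAcoa (1.99) and PbAcod (1.97), and PbIdh1b with 1.14 (FDR 0.0025). Centring left 3 of the 24 higher and 2 lower, and the list median lay inside the central 95% of both kinds of matched lists (percentiles 97.1 and 83.9). Among 92 mitochondrial respiration genes, 13 were lower and 6 higher (adjusted p = 0.0016 for lower calls). NDUFA4_2 fell by 2.61, INH1_2 by 1.64, Ndufs6 by 1.45 and NDUFB7 by 1.23, while QCR1_3 rose by 2.93, in the authors' deposited table. Adjusted over the list alone, 21 respiratory genes were lower and 7 higher, and under the F reference 4 were lower and 2 higher. Centring gave 32 lower and 2 higher, and taking out the trend on expression level and gene span left no direction, with 8 lower and 9 higher and a median of -0.04 in place of -0.35. The median lay at percentile 0 of lists matched on log2 CPM and at 10.9 of those matched on gene span too. In the authors' deposited table carC, of the carotene list, rose by 2.45 (FDR 1.9e-06), CarG2 fell by 3.86 (FDR 7.4e-13) and carRA2 fell by 1.13 (FDR 0.0153). The carotene and isoprenoid list of 8 genes had 1 higher and 2 lower and did not pass the list test (adjusted p = 0.248 for lower calls). Adjusted over the list alone, the count was also 1 higher and 2 lower.

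In total, 1421 genes were higher and 603 lower in light in wild type mycelium among 14410 in the authors' deposited table, so 70.2% of calls were higher. Among called genes without a symbol and with a log2 CPM of at least the table median, the largest rises and falls were those of PHYBLDRAFT_12373 (9.30), PHYBLDRAFT_11342 (8.74), PHYBLDRAFT_62767 (-5.50) and PHYBLDRAFT_151839 (-4.07), in the authors' deposited table. The median log2 fold change was 0 over all genes and 0.39 over genes with a fold other than 0. Relative to that shift, 907 genes were higher and 1344 lower (40.3% higher), and with the trend on expression level and span taken out 895 were higher and 1130 lower (44.2% higher). When the likelihood ratio was referred to an F distribution, 997 genes were called, and the calls of MadB, WctC, PPK2, Gpa1B and PHYBLDRAFT_62767 (adjusted p = 0.0982) ended.

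**Figure D2:**
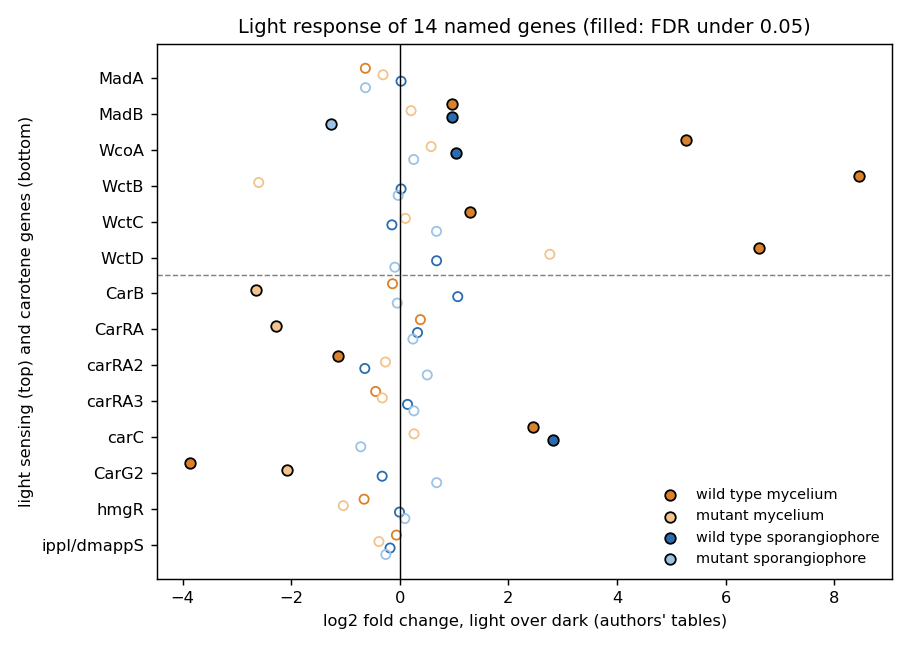
Log2 fold change, light over dark (horizontal axis), of the 6 light sensing and 8 carotene and isoprenoid genes (vertical axis) in the authors' deposited tables; colours mark the strain and structure, and filled points have an FDR under 0.05. WctB, WctD and WcoA lie furthest to the right in wild type mycelium, at 8.45, 6.61 and 5.28, while no light sensing gene is filled in mutant mycelium. MadB and WctC of wild type mycelium lose their calls after centring, and MadA becomes a lower call.

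In wild type sporangiophores, genes of mitochondrial respiration were called higher in light more often than other genes. Of 92 measured, 50 were higher, 1 lower and 41 not called (Fisher's exact test, adjusted p = 1.7e-31), with a median log2 fold change of 1.34 in the authors' deposited table. Fisher's exact test, here and for the other lists, treats genes as independent, so its p-value does not measure variation between libraries. Adjusted over the list alone, 64 were higher and 2 lower, and with the likelihood ratio referred to an F distribution 28 were higher and 0 lower. NDUFA4_3 rose by 3.65 (FDR 4.2e-04), SDHD, a succinate dehydrogenase subunit, by 2.91 (FDR 3.6e-07) and RIP1_2, a Rieske iron-sulfur subunit by its symbol, by 2.77 (FDR 1.4e-06) in the authors' deposited table. INH1 (2.67), NDUFS4 (2.53), COX9 (2.53), ATP17_2 (2.35), Ndufa5 (2.35) and ATP18_2 (2.10) were called higher in the same authors' deposited table. Highly expressed genes had higher folds here, with a median of 0.45 in the highest quintile of expression. With the trend on expression level and gene span taken out, 7 respiratory genes were higher and 1 lower, with a median of 0.43. The calls of SDHD (adjusted p = 0.0718), COX9 (0.0989), ATP17_2 (0.306) and ATP18_2 (0.480) then ended.

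Of the tricarboxylic acid cycle genes, 7 of 24 were higher and 0 lower in wild type sporangiophores (adjusted p = 0.0106). Their median of 0.45 lay at percentiles 14.3 and 44.8 of lists matched on log2 CPM and on log2 CPM and gene span, inside the central 95% of both. In the authors' deposited table PbAcoc, an aconitase by its symbol, rose by 2.25, Pb2oxodhE2 by 2.16, PbMdha by 1.62 and PbCsb by 1.28. Under the F reference 3 were higher. With the trend taken out 2 were higher and 1 lower, and PbMdha turned to -0.17 (adjusted p = 0.903). carC rose by 2.82 (FDR 1.7e-05), the single called gene of 8 in the carotene list, in the authors' deposited table. WcoA rose by 1.04 (FDR 0.0033) and MadB by 0.97 (FDR 0.0249) in the authors' deposited table. WctC (-0.14), WctD (0.68), WctB (0.02) and MadA (0.02) were not called in that authors' deposited table. The light sensing list did not pass its test, with 2 of 6 higher (adjusted p = 0.332), and adjusted over the list alone the count was also 2. Among protein kinases 2 of 36 were higher and 0 lower, and by the authors' edgeR test 0 of 11 G protein subunits were called (2 at an unadjusted p under 0.05), in the authors' deposited table. In all, 1042 genes were higher and 170 lower (86.0% higher) in the authors' deposited table. PHYBLDRAFT_79190 (4.77) and PHYBLDRAFT_159237 (4.56) rose furthest among called genes without a symbol and with a log2 CPM of at least the table median, and among the same genes PHYBLDRAFT_140593 (-1.52) and PHYBLDRAFT_104675 (-1.47) fell furthest, in the authors' deposited table. Over genes of any level, 41 called genes fell by at least 4-fold there. With the trend taken out, 307 were higher and 160 lower (65.7% higher), and the F reference left 482 calls, without WcoA, MadB, PbCsb and PHYBLDRAFT_104675 (adjusted p = 0.0917). MadB was not called with the trend taken out either.

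In mutant mycelium, some genes of the carotene list were called lower in light. CarB, the phytoene dehydrogenase gene, fell by 2.65 (FDR 1.3e-05), CarRA, the lycopene cyclase and phytoene synthase gene, by 2.28 (FDR 2.3e-04) and CarG2 by 2.07 (FDR 5.8e-04) in the authors' deposited table. These were the 3 called of 8 measured genes (Fisher's exact test for lower calls, adjusted p = 2.4e-04). Adjusted over the list alone 4 were lower, and under the F reference 0 were. Of 24 tricarboxylic acid cycle genes 3 were lower (adjusted p = 0.0035), namely PbAcoa (-2.29), PbIdh2c (-1.98) and PbAcod (-1.74) in the authors' deposited table. CaMK7 rose by 1.82 (FDR 0.0044) and NDUFA4_3 fell by 2.69 (FDR 6.4e-04) in the authors' deposited table. By the authors' edgeR test 0 of 6 light sensing genes were called, with 1 at an unadjusted p under 0.05, and WctD had 2.76 (FDR 0.309) in the authors' deposited table. WcoA had 0.58, MadB 0.21, WctC 0.10, MadA -0.31 and WctB -2.60 in the same authors' deposited table. In mutant mycelium 1 of 36 kinases, 0 of 11 G protein subunits (2 at an unadjusted p under 0.05) and 1 of 92 respiratory genes were called in the authors' deposited table.

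Across 14242 genes of mutant mycelium, 77 were higher and 82 lower (48.4% higher) in the authors' deposited table, and 1327 had an unadjusted p under 0.05. PHYBLDRAFT_124492 (9.04) and PHYBLDRAFT_157726 (8.26) rose furthest among called genes without a symbol and with a log2 CPM of at least the table median, and among the same genes PHYBLDRAFT_179633 (-5.69) and PHYBLDRAFT_108956 (-3.51) fell furthest, in the authors' deposited table. Centring gave 66 higher and 113 lower (36.9% higher), and taking out the trend 66 higher and 116 lower (36.3% higher). Under the F reference 10 genes were called, and the calls of CarB, CarRA, CarG2, CaMK7, NDUFA4_3, PHYBLDRAFT_179633 (adjusted p = 0.335) and the tricarboxylic acid cycle genes ended. The 12 degrees of freedom of that reference may be too many here, since this table came from another fit, and also for the other tables.

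In mutant sporangiophores, the same respiratory list was lower in light. Of 92 genes, 66 were lower and 1 higher (Fisher's exact test, adjusted p = 5.9e-38), with a median log2 fold change of -1.71 in the authors' deposited table. Adjusted over the list alone, 70 were lower and 2 higher, and under the F reference 59 were lower and 0 higher. NDUFA4 fell by 4.97 (FDR 1.3e-40), ATP5, a subunit of ATP synthase by its symbol, by 4.67 (FDR 8.7e-17) and ATP17_2 by 4.31 (FDR 8.2e-28) in the authors' deposited table. COX6B_2 (-4.04), RIP1_2 (-3.97), NDUFA4_3 (-3.90), ATP20 (-3.80) and ATP18_2 (-3.28) were called lower in the same authors' deposited table. Highly expressed genes had lower folds in this table, with a median of -0.47 in the highest quintile of expression. With the trend on expression level and span taken out, 37 respiratory genes were lower and 5 higher, with a median of -0.76. The direction of this table rests on its title alone, and with its sign turned the list would be higher in light.

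Tricarboxylic acid cycle genes were lower for 10 of 24 and higher for 0 in mutant sporangiophores (adjusted p = 0.0035), with the median at percentiles 70.9 and 29.9 of the 2 kinds of matched lists. PbIdh2a fell by 3.52, while Pb2oxodhE2 (-3.47), PbPdhE1b (-2.56) and PbIdh1a (-2.31) were also lower in the authors' deposited table. With the trend taken out, 4 were lower and 1 higher, the list median turned from -0.56 to 0.13, and PbPdhE1b was no longer called. MadB fell by 1.26 (FDR 0.0092) in the authors' deposited table, a call that ended under the F reference (adjusted p = 0.0590) and with the trend taken out. The other light sensing genes, WcoA (0.26), WctC (0.68), WctD (-0.09), WctB (-0.03) and MadA (-0.63), were not called in the authors' deposited table. PKC1 (0.62, FDR 0.0488) and PkaR2 (0.64, FDR 0.0362), a regulatory subunit of cAMP-dependent kinase by its symbol, were called higher in the authors' deposited table, and both calls ended after centring and under the F reference. Of 36 kinases 1 was higher and 4 lower, of 11 G protein subunits 2 were lower, and of 8 carotene genes 0 were called (0 at an unadjusted p under 0.05) in the authors' deposited table. In all, 477 genes were higher and 1779 lower (21.1% higher) in the authors' deposited table, and 642 were higher and 1275 lower (33.5% higher) with the trend taken out. With the sign of this table turned, 1779 would be higher and 477 lower (78.9% higher). PHYBLDRAFT_164420 (-7.21) and PHYBLDRAFT_136423 (-6.80) fell furthest among called genes without a symbol and with a log2 CPM of at least the table median, and among the same genes PHYBLDRAFT_133191 (1.77) and PHYBLDRAFT_167695 (1.77) rose furthest, in the authors' deposited table. Over genes of any level, 101 called genes rose by at least 4-fold there. Under the F reference the call of PHYBLDRAFT_133191 ended (adjusted p = 0.0866).

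**Figure D3:**
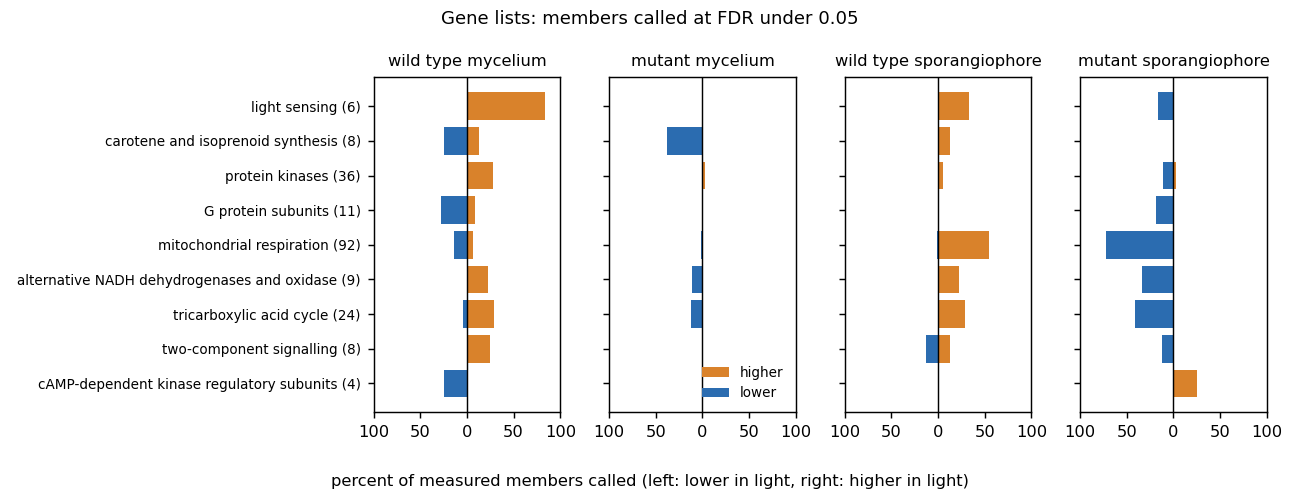
Percent of measured members called at an FDR under 0.05 (horizontal axis; left of 0, lower in light; right, higher in light) for 9 gene lists with the number measured in brackets (vertical axis), in the authors' deposited tables of the 4 strain and structure pairs. Of the 92 mitochondrial respiration genes, 50 are higher in wild type sporangiophores and 66 lower in mutant sporangiophores. With the trend on expression level and gene span taken out these counts are 7 and 37, and the respiratory genes of wild type mycelium keep no direction (9 higher and 8 lower).

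The light responses of the strains were compared in mycelium by an approximate test of the difference between the fold changes of the authors' deposited tables, chosen after seeing the data. The mutant mycelium table came from a separate fit, since its log2 CPM differed for all 14162 shared genes. The difference, wild type minus mutant, was higher for 1055 and lower for 457 of 10462 genes. That excess of higher differences was not kept under other scaling, with 647 higher and 592 lower once the trend on expression level and gene span was taken out and 733 higher and 737 lower after centring. Differences were called for 3 of 6 light sensing genes: WctB (11.05, adjusted p = 5.9e-05), WcoA (4.70, adjusted p = 1.3e-10) and WctD (3.85, adjusted p = 0.0211). By this test the difference was positive for the carotene genes CarRA (2.66), CarB (2.51) and carC (2.19) and negative for CarG2 (-1.79). CarRA (0.38) and CarB (-0.13) were not called in wild type mycelium, and their differences came from the falls in the mutant (-2.28 and -2.65). carC rose in the wild type (2.45 against 0.26), and CarG2 fell in both strains (-3.86 and -2.07). PPK2 (5.84), Gpb3 (5.25) and PPK3 (4.82) had the largest positive and INH1 (-3.31), Gpa1B (-2.39) and NDUFA4_2 (-2.13) the largest negative differences under the naming rule. For the 1421 genes higher in wild type mycelium, the median in mutant mycelium was -0.15, and 22 were called higher and 29 lower there in the authors' deposited tables. Independent lists would share 7.73 and 8.23 genes, and lists matched on expression 12.6 and 14.8.

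In sporangiophores the difference, wild type minus mutant, was higher for 2020 and lower for 799 of 14401 genes. It was higher for 1404 and lower for 949 with the trend taken out, and for 2140 and 611 after centring. Of 92 respiratory genes, 70 had a higher and 2 a lower difference, with a median of 3.07. Taking out the trend moved their median fold from 1.34 to 0.43 in the wild type and from -1.71 to -0.76 in the mutant. NDUFA4_3 (7.55), RIP1_2 (6.73) and ATP17_2 (6.66) had the largest positive differences under the naming rule, and MKL2 (-1.41), PkaR2 (-1.27) and QCR1_4 (-1.01) the largest negative ones. carC (3.54) and MadB (2.23) also differed. These values depend on the direction of the mutant table, which rests on its title alone. With its sign turned, the difference would be higher for 40 and lower for 273 genes, and of the respiratory genes 0 would be higher and 5 lower, with a median of -0.37. NDUFA4_3 would then have -0.25, RIP1_2 -1.20 and ATP17_2 -1.95, MKL2 -0.41, PkaR2 0.01 and QCR1_4 -0.36, carC 2.11 and MadB -0.29, and among these 8 genes only ATP17_2 would be called (adjusted p = 0.0266). Across genes, which are not independent replicates, the fold changes of the authors' deposited tables had a Spearman correlation of -0.47. Of the 842 genes called in both strains, 842 had opposite signs in the authors' deposited tables. Of these, 810 were higher in the wild type and lower in the mutant, against 128.6 for independent lists and 427.7 for lists matched on expression.

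**Figure D4:**
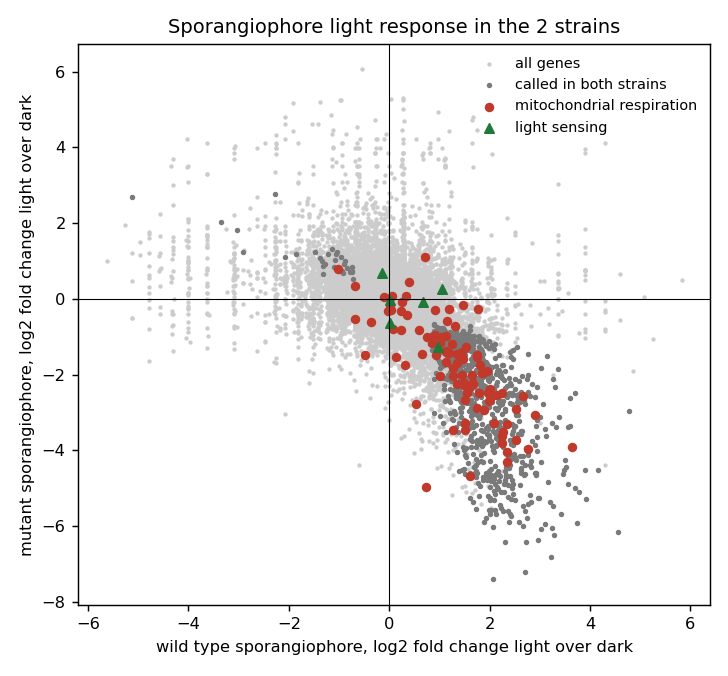
Log2 fold change, light over dark, of each gene in wild type (horizontal axis) and mutant (vertical axis) sporangiophores in the authors' deposited tables; dark grey marks the 842 genes called in both, red the 92 respiratory genes and green triangles the 6 light sensing genes. Genes called in both lie in the upper left or lower right, and the Spearman correlation across genes is -0.47.

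The light responses of the wild type structures, sporangiophore minus mycelium, differed upward for 1174 and downward for 1059 of 11213 genes by the same approximate test. With the trend taken out these counts were 884 and 628, and after centring 1787 and 621. Respiratory genes had a higher difference for 48 and a lower one for 1 of 92. Taking out the trend moved their median fold from 1.34 to 0.43 in sporangiophores and from -0.35 to -0.04 in mycelium. NDUFA4_2 (4.07), Cam1 (3.89) and NDUFA4_3 (3.77) had the largest positive differences under the naming rule, and Gpb3 (-6.48), PPK2 (-6.03) and WctD (-5.93) the largest negative ones. WctB (-8.43) and WcoA (-4.24) also responded less in sporangiophores, and CarG2 (3.54) differed upward. Genes higher in both structures numbered 114 in the authors' deposited tables, against 102.8 for independent lists and 173.7 for lists matched on expression. These included WcoA, MadB, carC, CaMK2, NDE2, Hpt_2, SDH1, COX4_2, QCR1_2 and NDUFS7. Lower in mycelium but higher in sporangiophores were 131 genes, against 43.6 for independent lists and 113.9 for lists matched on expression, in the authors' deposited tables.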

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

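The difference tests behind the values here were chosen after the data were seen, and so was the comparison of genes at a fold of 0, while the test on the lowest quintile of expression was added after the 114-gene median was known, and the comparison of covariances by quintile and the turned sign were added after all values had been seen. The counts and genes below were picked up because the light response differed between strains or structures by the approximate test of the difference. Genes are those of the naming rule for differences and the light sensing and carotene lists, and other genes enter only through the counts.

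In mycelium, wild type minus mutant, 1512 genes differed. Their named members were WctB (11.05), PPK2 (5.84), Gpb3 (5.25), PPK3 (4.82), WcoA (4.70), WctD (3.85), CarRA (2.66), CarB (2.51) and carC (2.19). Negative differences were those of CarG2 (-1.79), NDUFA4_2 (-2.13), Gpa1B (-2.39) and INH1 (-3.31). In sporangiophores, wild type minus mutant, 2819 genes differed, among them NDUFA4_3 (7.55), RIP1_2 (6.73), ATP17_2 (6.66), carC (3.54), MadB (2.23), QCR1_4 (-1.01), PkaR2 (-1.27) and MKL2 (-1.41). In the wild type, sporangiophore minus mycelium, 2233 genes differed. Positive values were those of NDUFA4_2 (4.07), Cam1 (3.89), NDUFA4_3 (3.77) and CarG2 (3.54), and negative ones those of WcoA (-4.24), WctD (-5.93), PPK2 (-6.03), Gpb3 (-6.48) and WctB (-8.43).

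All 842 genes called in sporangiophores of both strains had opposite signs in the authors' deposited tables. A trend with expression level and gene length as the whole cause is argued against, since the Spearman correlation across genes stayed at -0.38 after the trend was taken out. Of the 842 genes 770 were still opposite, but they were picked by their calls and all started opposite, so that count is no test. Noise of libraries shared with opposite sign is argued against as the whole cause too, but only for genes in the highest quintile of expression. The correlation in the lowest quintile of expression was -0.11 (95% bootstrap interval -0.15 to -0.07), weaker than the bound of -0.15 written beforehand, with the end of the interval close to that bound. Genes of the lowest quintile lie near the count floor, so that value decides nothing. The correlation strengthened over -0.27, -0.41 and -0.53 to -0.70 in the highest quintile. There the covariance was -0.63 (-0.68 to -0.57) against a size of 0.0749 for the part of the mean squared standard error that shared light libraries would bring. These intervals resample genes and do not measure variation between libraries. A turned sign of the mutant table stays open, as does a real opposite response of the mutant. Of 29 genes called the same way in both mycelium tables, 27.6% had the same sign in the mutant sporangiophore table. In the wild type sporangiophore table the share was 75.9%. These are too few genes to decide. With the sign turned, 313 genes differed between the strains in place of 2819. Folds of opposite sign give such a drop whatever their cause, so this count cannot tell a turned sign from a real opposite response. Wild type light libraries entering the mutant comparison also cannot be told apart from a turned sign or a real opposite response. The 114 genes higher in both wild type structures had a mutant sporangiophore median of -1.24, a value that met the prediction for such a mix-up but that every explanation left open gives. In the lowest quintile the covariance was -0.16 (-0.22 to -0.10), against a size of 0.68 for the part that shared light libraries would bring. That is less than a full mix-up would bring, but these genes lie near the count floor, so it decides nothing.

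Respiratory genes were higher in wild type and lower in mutant sporangiophores, with medians of 1.34 and -1.71 in the authors' deposited tables. A trend with expression level and gene length may account for much of this: the medians of matched random lists were 1.03 and -1.21, and the list lay at the 97.54 and 2.46 percentiles of lists matched on level and span, although lists matched on level alone had medians of 0.52 and -0.53 and left it at percentiles 100 and 0. The first pair lie past the central 95% by less than the error of drawing 10000 lists, so the trend as the whole cause cannot be told apart from a response of the list itself. Across genes the fold hardly followed gene span alone, with Spearman correlations of -0.04 in wild type and 0.02 in mutant sporangiophores. What the matching on span adds to that on level was not tested. The photoreceptor genotype and growth stage remain untested biological explanations, and the open explanations of the opposite signs apply here too.

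In mycelium, 2026 genes had a fold of exactly 0 in both authors' deposited tables, against 577.6 expected for independent lists. Such genes may have had no reads in the mycelium libraries, and the 3193 genes at 0 in wild type mycelium had a median log2 CPM of 2.56 against 5.19 for other genes, a difference of -2.63. Values per library, which would settle this, were not analysed here, and no biological explanation was tested.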

How the results depend on the processing

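The difference tests and the centring, trend, turned sign, F reference, table-median filter and 2 adjustment alternatives were chosen after the data were seen. Under an FDR of 0.01 the counts were 1252 in wild type mycelium, 736 in wild type sporangiophores, 64 in mutant mycelium, 777 for the strain difference in mycelium, 1270 for the structure difference, 55 higher in both wild type structures, 46 lower in mycelium but higher in sporangiophores, and 10 higher in mycelium of both strains; fewer genes pass by construction. At that threshold the adjusted p of the list tests was 0.425 for kinases, 0.0547 for respiration and 0.145 for the tricarboxylic acid cycle in wild type mycelium, and 0.199 for the tricarboxylic acid cycle in wild type sporangiophores. With an absolute log2 fold change of at least 1, kinases (0.0918) and the tricarboxylic acid cycle (0.111) of wild type mycelium no longer passed. The F reference gave 997 calls in wild type mycelium, 482 in wild type sporangiophores and 10 in mutant mycelium, while the 1514 in mutant sporangiophores stayed within 1.5 times. With the trend taken out 467 genes were called in wild type sporangiophores, of which 355 were among the main calls, and PbMdha, WT sporangiophore, turned to -0.17; the cause was not tested. With the sign of the mutant sporangiophore table turned, the strain difference in sporangiophores fell to 313 genes from 2819. Of 95 named-gene results, 79 were called. Of these 79, 9 lost their call at an FDR of 0.01, 4 with a log2 fold change of at least 1, 2 with the median filter, 22 under the F reference, 5 after centring and 11 after the trend was taken out, and 1 turned sign. MadA in wild type mycelium became a call after centring and after the trend was taken out. The log2 CPM minimum of 1 removed no gene, so it tested nothing. The count-based alternatives (DESeq2, RLE scaling, count filters, the replicate block, leaving out replicates, putting back libraries, the exact test, a joint fit, pseudocounts, camera and fry) and other splits of the samples were not run, since they need values per library. No paired analysis was possible because the tables carry no replicate columns. Depth per library is unknown here, and folds of genes with low log2 CPM, such as WctB, are limited by it.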

Other observations

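The values here were looked at after the main results were known, and the families were picked by shared symbol after many of their values had been seen. Apart from the Wct genes, copies within a family differed in their calls in the authors' deposited tables. In wild type mycelium 3 of 3 Wct genes were higher, while 0 of 3 were called in the other comparisons of the authors' deposited tables. After centring, the call of WctC (adjusted p = 0.154) ended. Of 4 aconitase genes 3 were higher in wild type mycelium, and in the authors' deposited tables PbAcoc was the 1 called in wild type sporangiophores (2.25) and in mutant sporangiophores (-2.47). In mutant mycelium 2 aconitase genes, PbAcoa and PbAcod, were lower in the authors' deposited table. Of 4 Gpb genes, Gpb3 was higher (6.73) and Gpb1 lower (-3.08) in wild type mycelium, and Gpb1 (-0.72) and Gpb2 (-1.11) were lower in mutant sporangiophores, in the authors' deposited tables. Of 3 NDUFA4 genes, the calls in the authors' deposited tables were NDUFA4_2 (-2.61) in wild type mycelium, NDUFA4_3 in wild type sporangiophores (3.65) and mutant mycelium (-2.69), and NDUFA4 (-4.97) and NDUFA4_3 (-3.90) in mutant sporangiophores. No test of differences between copies was run, and reads shared between near-identical copies were not examined.

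Some genes of no list, and the lists that passed no test, also held calls. Of the 3 leu genes, which belonged to no list, had no list test and were chosen after their values were seen, leuC fell by 3.03, leuA by 1.25 and leuB/leu1 by 1.19 in mutant sporangiophores in the authors' deposited table. In the other authors' deposited tables leuB/leu1 rose by 1.56 in wild type mycelium and fell by 1.59 in mutant mycelium, and leuC rose by 1.32 in wild type sporangiophores. Alternative NADH dehydrogenases and oxidase had 2 of 9 higher in each wild type structure, 1 lower in mutant mycelium and 3 lower in mutant sporangiophores, and passed no list test (adjusted p = 0.721, 0.536, 0.281 and 0.408). Among these, NDE2 had 1.52 in wild type mycelium and -1.72 in mutant sporangiophores, and AOX, the alternative oxidase, -2.07 in mutant sporangiophores, in the authors' deposited tables. For 2-component signalling 2 of 8 genes were higher in wild type mycelium, 1 higher and 1 lower in wild type sporangiophores, 0 called in mutant mycelium and 1 lower in mutant sporangiophores in the authors' deposited tables. Of 4 cAMP-dependent kinase regulatory subunits, PkaR1 (-0.83) was lower in wild type mycelium and PkaR2 higher in mutant sporangiophores in the authors' deposited tables. Of 2 RNA silencing genes, RdRP-1a was the 1 called, in wild type mycelium, in the authors' deposited tables. Among the 131 genes lower in wild type mycelium and higher in wild type sporangiophores, 8 belonged to the respiratory list.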
